A study of Mus musculus with 10 samples.

How the data were processed

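RNA sequencing libraries of sorted tumour epithelial cells were analysed, 10 in all, 5 in each of 2 groups. Per the labels, T6-LOH organoids were the source of the epithelial cells. The organoids were transplanted into the pancreas of mice together with pancreatic stellate cells (PSCs), the resident fibroblast precursors of the pancreas. The PSCs were either a Rosa control line, read here as Egfr WT PSC, or the Egfr knockout clone B4 (Egfr KO PSC). Only 1 knockout clone was used. The tumours were sorted by flow cytometry and the epithelial fraction was sequenced. The markers used for the sort are not given in the sources used here. Per the labels' protocols, RNA was collected in TRIzol, purified with a micro column kit and turned into libraries with a single-cell and low-input kit. The number of PCR cycles depended on the RNA input, and the input of each library is not given in the sources used here. Duplicate molecules cannot be told apart without molecular identifiers, so all intervals cover counting error and the spread between libraries together.

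The authors deposited one transcript quantification per library, with the estimated count of each transcript, its effective length and its TPM. Per the submitters' processing notes these expected counts came from Salmon 1.9.0 with a GRCm39 reference, and the annotation release is not given in the sources used here. The deposited estimated counts are not normalised and need not be whole numbers. The deposited TPM values were not used here, and the effective lengths entered 1 alternative. Each library lists the same 147828 transcripts.

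Transcripts were assigned to genes by their identifier without the version number, with the GENCODE M21 annotation of GRCm38. Only names were taken from this annotation, because the quantification used another build, and no coordinates are reported. Of the 147828 transcripts, 137063 (92.7%) had a gene in it, and they held between 98.1% and 98.7% of the estimated counts of a library. The other 10765 transcripts were left out of library sizes and of the gene tests and were examined separately. Estimated counts were summed per gene and rounded to whole numbers. Genes that share sequence, such as the 2 alpha-globin genes, the ribosomal protein genes and their processed copies, or the MHC genes, depend on how the quantification divided shared reads, and their separate values are uncertain. The totals lay between 39534000 and 53816000 counts per library.

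Groups were taken from the labels. The labels pair no library of one group with a library of the other, and the replicate numbers only name libraries. They also do not say that each library came from a separate mouse, so p-values measure the spread between these libraries. No 2 libraries agreed within sampling noise: the lowest chi-square per degree of freedom over genes for any pair was 38.9. This argues only against 1 library deposited under 2 names, and does not bear on whether the libraries came from separate mice. Correlations of log2 CPM between libraries lay between 0.956 and 0.985.

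The comparison of Egfr KO PSC with Egfr WT PSC was fitted with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation, the default expression filter (minimum count 10) and no covariate. P-values were adjusted by the Benjamini-Hochberg method over the 17495 genes tested, with a threshold of 0.05. Standard errors (SE) were derived from the F statistic, and 95% confidence intervals from its degrees of freedom. All fold changes are log2 of Egfr KO PSC over Egfr WT PSC. Levels are TMM-normalised counts scaled to a fixed library total (CPM), given as the mean ± SD of 5 libraries. The median log2 fold change of all genes was 0.00041.

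Before the data were examined, 38 gene lists were fixed, 23 of tumour cell programmes and 15 of cell types. They held 857 names, of which 855 were matched to a gene, and 4 of these matched a gene that the same list already held, which left 851 memberships. A total of 41 genes stood in more than 1 list. The lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted separately over programme lists and over cell type lists. The lymphocyte list had fewer than 3 members above the filter and was not tested, which left 14 cell type lists. Members were also adjusted over the list alone. A list score is the mean log2 CPM of its members in a library, with a prior count of 2. Scores and library measures were compared by exact two-sided permutation tests over all 252 assignments of 5 against 5, which cannot give a p below 0.00794.

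The rule for the genes named in the report was also fixed beforehand. It took up to 12 genes past the threshold in each direction, those of largest change with a mean of at least 5 CPM. Where fewer than 6 passed, it added the genes of lowest p at that level until 6 were named. Predicted genes and pseudogenes were counted but not named in these steps. It took the 4 members of lowest p from each called list, and allowed the member of lowest p from each other programme list. It also took the EGFR family receptors and ligands, 3 genes tied to the organoid line, and 5 genes that check the sort. Some genes that the rule took are not reported here. Genes named outside this rule were chosen after their values were seen and are identified as such.

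The steps were tested on simulated data: counts were drawn from the means and dispersions of these libraries, with 50 genes changed at each of 4 fold sizes. Of the 17100 genes that passed the filter there, the test called 16% of the genes changed 1.5-fold, 48% of those changed 2-fold, 80% of those changed 3-fold and 92% of those changed 4-fold. It called 5 of 16880 unchanged genes. The adjusted threshold is stricter where fewer genes change, so these shares hold for this number of changed genes only. In the same simulated data 1 list was shifted as a whole, with genes drawn independently. The camera test recovered the shifted list and called 1 other list. In the real libraries the estimated correlation within a list lay between 0.031 (EGFR family) and 0.78 (mitosis and G2). The simulation therefore does not show how camera performs on lists of correlated genes.

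The alternatives fixed beforehand were median-of-ratios size factors, no filter, a stricter filter (CPM of at least 1 in 5 libraries), an offset for transcript length, DESeq2 1.42.0, limma voom with sample weights, and protein-coding genes only. They also covered 3 covariates (genes detected, the fibroblast list score, and the number in the file name), leaving out each library in turn, and, for lists, camera with an estimated correlation, fry, and the exact test of list scores. After the data were seen, 3 alternatives were added. They were leaving out Egfr WT PSC replicate 5 and Egfr KO PSC replicate 3 together, 1 surrogate variable from sva 3.50.0, and the macrophage list score as a covariate. Each of these 2 libraries was the highest of its group on the first principal component (35.4 and 67.7). Egfr KO PSC replicate 4, at 41.1, lay above Egfr WT PSC replicate 5 and was kept. No result is given for a list with its own score as the covariate, although that list stayed among those adjusted over. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.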

Results

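The data were 10 transcriptomes of epithelial cells sorted from pancreatic ductal adenocarcinoma (PDAC) grown in mice. The series title names NSG mice, an immunodeficient strain, while the strain label of every library is C57BL/6J, without saying whether it means the host or the transplanted cells. The tumours came from KPC organoids, a genetic mouse model of PDAC, injected into the pancreas together with pancreatic stellate cells (PSCs). The PSCs were a Rosa control line in 5 libraries, read as the Egfr WT PSCs of the series title, and a single Egfr knockout clone of the same PSC line in the other 5 (Egfr KO PSC). The total estimated count in genes was 46313000 ± 5071700 per library with Egfr WT PSCs and 46594000 ± 5686500 with Egfr KO PSCs (mean ± SD, n = 5 each; exact permutation p = 0.944). The number of genes detected was 26596 ± 503 and 26598 ± 298 (exact permutation p = 0.992). The mitochondrial share was 3.17 ± 1.04% and 2.56 ± 0.365% (exact permutation p = 0.286). The 50 most abundant genes held 19.6 ± 0.801% and 18.7 ± 1.80% of the counts (exact permutation p = 0.294). Clu, which encodes the secreted chaperone clusterin, was the most abundant gene in every library, at 1.78% to 4.62% of the counts.

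The design has a single comparison, which asks how the loss of Egfr in the co-transplanted PSCs changes gene expression in the tumour epithelial cells. With 1 knockout clone, an effect of Egfr loss and an effect of the clone cannot be separated by this design. Egfr itself was measured at 58.5 ± 16.2 CPM with Egfr WT PSCs and 63.4 ± 9.12 CPM with Egfr KO PSCs (log2 fold change 0.12, 95% confidence interval -0.28 to 0.52, edgeR adjusted p = 0.891). The single libraries lay at 75.0, 39.8, 58.4, 74.1 and 45.2 CPM with Egfr WT PSCs and at 67.0, 76.7, 52.2, 59.5 and 61.9 CPM with Egfr KO PSCs. The knockout was made in the PSCs and not in the sorted cells, so these values do not check the labels. The log2 fold change of Egfr was -0.11 with the fibroblast score as a covariate and -0.17 with the macrophage score as one. The related receptors Erbb2 (62.2 ± 4.68 and 56.7 ± 8.93 CPM) and Erbb3 (150.5 ± 30.2 and 161 ± 35.1 CPM) did not pass the test either. Among the EGFR ligands, Hbegf was the most abundant and had the lowest p, at 747 ± 121 CPM with Egfr WT PSCs and 611 ± 74.3 CPM with Egfr KO PSCs (log2 fold change -0.29, SE 0.13, edgeR adjusted p = 0.604). Tgfa was at 36.7 ± 6.67 and 45.1 ± 9.25 CPM, and Btc at 87.2 ± 18.7 and 93.3 ± 14.1 CPM. Ereg was at 41.1 ± 11.9 and 50.1 ± 15.2 CPM, and Areg at 10.1 ± 1.48 and 13.2 ± 7.03 CPM. Egf was lowest, at 1.40 ± 0.378 and 1.29 ± 0.519 CPM, and these 5 ligands had adjusted p of 0.673 or more. Epgn had 2 to 12 counts per library and was below the filter. The list of EGFR family receptors and ligands was not called (11 members tested, 7 higher and 4 lower, camera adjusted p = 0.77).

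**Figure D1:**
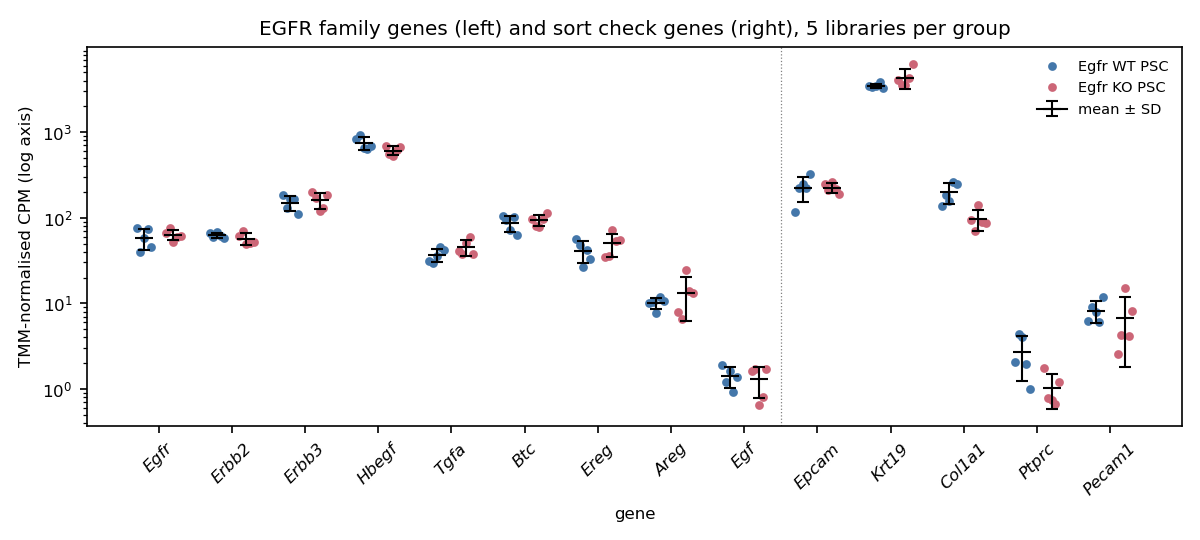
TMM-normalised CPM on a log axis of EGFR family genes and of genes that check the sort, one point per library, with the mean and SD of the 5 libraries of each group in black. Epcam and Krt19 were measured in every library of both groups, and the mean of Col1a1 was 199 CPM with Egfr WT PSCs and 96.6 CPM with Egfr KO PSCs, a difference that did not pass over all genes with edgeR (adjusted p = 0.321) and passed with DESeq2 (adjusted p = 0.00643).

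Epithelial marker genes were abundant in all libraries. Epcam, an epithelial surface protein, was at 225 ± 73.2 and 225 ± 29.8 CPM, and the ductal keratin gene Krt19 at 3466 ± 216 and 4339 ± 1106 CPM with Egfr WT and Egfr KO PSCs. The leukocyte gene Ptprc was at 2.68 ± 1.45 and 1.03 ± 0.448 CPM, the endothelial gene Pecam1 at 8.23 ± 2.37 and 6.79 ± 4.99 CPM, and the collagen gene Col1a1 at 199 ± 55.2 and 96.6 ± 27.2 CPM. Some other members of the cell type lists were more abundant, with Aqp1 of the endothelial list at 79.5 ± 26.6 and 50.4 ± 28.8 CPM and Cd74 of the MHC class II list at 26.9 ± 13.0 and 14.8 ± 9.34 CPM. Carcinoma cells may express some list members themselves, so these levels need not come from other cells. Trp53 (116 ± 8.92 and 114 ± 15.7 CPM) and Cdkn2a (76.8 ± 13.5 and 92.7 ± 14.6 CPM) were measured in every library, with adjusted p of 0.67 or more.

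With edgeR no single gene passed the threshold between the groups, while DESeq2 called 127 genes and limma voom 3. The gene closest to it was the interferon-induced gene Ifi27, at 48.7 ± 7.97 CPM with Egfr WT PSCs and 22.5 ± 3.47 CPM with Egfr KO PSCs (log2 fold change -1.11, SE 0.15, edgeR adjusted p = 0.105). DESeq2 (adjusted p = 5.1e-08) and limma voom (adjusted p = 0.0353) called it. All 5 libraries with Egfr KO PSCs lay below all 5 with Egfr WT PSCs. Among the lower genes with a mean of at least 5 CPM, the 6 of lowest p also included the transcription factor genes Onecut3 (9.08 ± 1.61 and 3.46 ± 1.03 CPM) and Zbtb20 (84.4 ± 14.2 and 55.6 ± 5.72 CPM). The matrix genes Ccdc80 (44.2 ± 16.3 and 18.0 ± 5.02 CPM) and Col1a1 were in that group as well, and so was Serpinb9 (47.5 ± 7.11 and 28.9 ± 4.49 CPM), which encodes an inhibitor of granzyme B. Among the genes higher with Egfr KO PSCs, Id3, an inhibitor of basic helix-loop-helix transcription factors, was at 51.8 ± 4.18 and 117 ± 37.4 CPM (log2 fold change 1.18, SE 0.20, edgeR adjusted p = 0.225). Aqp3, a water and glycerol channel gene, was at 25.2 ± 4.63 and 111 ± 75.2 CPM (log2 fold change 2.13, SE 0.40, edgeR adjusted p = 0.304). The cytoskeletal gene Add2 was at 53.5 ± 13.8 and 97.7 ± 16.0 CPM, and the DNA repair gene Rad18 at 42.6 ± 4.35 and 67.9 ± 13.1 CPM. The lysosomal protease gene Ctsl (357 ± 48.4 and 545 ± 72.6 CPM) and Nme2 (113 ± 16.7 and 167 ± 18.7 CPM), a nucleoside diphosphate kinase gene, completed the 6 of lowest p. DESeq2 called all 12 of these genes, but they were chosen for low p in the same counts, so this adds no separate support.

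Over the 17495 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes, against 1426 at an unadjusted p under 0.05 (621 higher and 805 lower with Egfr KO PSCs), where chance would give 875. The 2 groups did not overlap in 266 genes (1.52%), and chance gives 0.794%. Both chance values are averages and do not show an excess by themselves. Of 100 splits of these libraries, the real one included, 18 gave at least 1426 genes at an unadjusted edgeR p under 0.05. Genes without overlap were not counted in other splits. With the macrophage score as a covariate 790 genes had an unadjusted edgeR p under 0.05, fewer than the 875, and with the fibroblast score 1733 had. DESeq2 called 127 genes, 42 higher and 85 lower, and limma voom with sample weights called 3, namely Id3, Onecut3 and Ifi27. Without Egfr KO PSC replicate 1, edgeR called 4 genes, all lower: Ifi27, Onecut3, Fabp7 and Rgs13. Without Egfr WT PSC replicate 5 it called Ifi27 and the unnamed gene Gm15663, both lower, and without Egfr KO PSC replicate 3 it called 1 gene, Id3, which was higher. Fabp7, Rgs13 and Gm15663 are named because they were called there, and were chosen after their values were seen.

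Genes of the type I interferon response fell with Egfr KO PSCs as a list: 28 of its 31 members tested were lower and 3 higher, with a mean log2 fold change of -0.47 (camera adjusted p = 1.16e-10). The call was lost with an estimated correlation (adjusted p = 0.626 with an estimated correlation). The list score was 2.67 ± 0.190 with Egfr WT PSCs and 2.15 ± 0.396 with Egfr KO PSCs (n = 5 each; exact permutation p = 0.0476, unadjusted). Besides Ifi27, the members of lowest p included the interferon regulatory factor gene Irf1 (95.2 ± 13.7 and 71.6 ± 10.9 CPM) and the antiviral gene Oas1g (3.40 ± 0.843 and 1.53 ± 0.966 CPM). Adjusted over the list alone, 2 members passed, Ifi27 among them, against 0 over all genes tested with edgeR. The macrophage list was lower with Egfr KO PSCs in the same libraries, with a mean log2 fold change of -0.79 (-0.44 without Egfr WT PSC replicate 2).

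Genes of MHC class I antigen presentation and of NF-kB and inflammatory cytokines also fell as lists. In the MHC class I list 15 of 16 members were lower (mean log2 fold change -0.24, camera adjusted p = 0.0194, adjusted p = 0.675 with an estimated correlation). Its members of lowest p were Pdia3 (754 ± 225 and 548 ± 126 CPM) of the peptide-loading complex and the peptide transporter gene Tap2 (18.3 ± 5.04 and 12.6 ± 5.17 CPM). They were followed by B2m (319 ± 40.5 and 279 ± 23.6 CPM), the light chain of MHC class I, and the immunoproteasome gene Psmb9 (1.53 ± 0.495 and 1.03 ± 0.463 CPM). In the NF-kB list 22 of 30 members were lower (mean log2 fold change -0.23, camera adjusted p = 0.00453, adjusted p = 0.675 with an estimated correlation). The macrophage growth factor gene Csf1 was at 9.27 ± 2.70 and 4.55 ± 0.788 CPM and the adhesion gene Icam1 at 181 ± 38.9 and 109 ± 19.7 CPM, and both passed when adjusted over the list alone and with DESeq2 over all genes. Birc3 (37.5 ± 1.82 and 31.8 ± 2.39 CPM), an inhibitor of apoptosis, and the chemokine gene Cxcl16 (141 ± 28.0 and 109 ± 15.6 CPM) followed. For the NF-kB and inflammatory cytokines list, the call was lost without Egfr WT PSC replicate 5 (mean -0.071) and without Egfr KO PSC replicate 1 (mean -0.16). It was kept without Egfr KO PSC replicates 2, 3 or 5, with means of -0.15, -0.50 and -0.15. The MHC class I call was lost without Egfr WT PSC replicate 3 (mean -0.22) and without Egfr KO PSC replicates 2 (mean -0.19) or 4 (mean -0.17). With the fibroblast score as a covariate both lists lost the call, with a mean of -0.14 for the MHC class I antigen presentation list and of 0.18, on the other side of 0, for the NF-kB and inflammatory cytokines list. Both also lost it with the macrophage score as a covariate (means -0.15 and -0.065). The MHC class I list lost it further with 1 surrogate variable (mean -0.23) and without Egfr WT PSC replicate 5 and Egfr KO PSC replicate 3 together (mean -0.25). The NF-kB mean was -0.45 with 1 surrogate variable. The fibroblast and macrophage lists were lower with Egfr KO PSCs in the same libraries.

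The dissociation and immediate early stress list fell as well: 20 of 26 members were lower (mean log2 fold change -0.26, camera adjusted p = 0.00232, adjusted p = 0.675 with an estimated correlation). The cytokine signalling inhibitor gene Socs3 was at 160.0 ± 67.0 and 76.8 ± 29.8 CPM, and the early response gene Ier2 at 134 ± 65.4 and 55.3 ± 22.5 CPM. The transcription factor gene Junb was at 696 ± 322 and 381 ± 135 CPM, and Jun at 125 ± 22.3 and 94.3 ± 16.4 CPM. The exact permutation p of the list score was 0.0794. The call of the dissociation and immediate early stress list was lost with the fibroblast score (mean -0.16) and with the macrophage score (mean -0.14) as a covariate, and both of these cell type lists were lower with Egfr KO PSCs.

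The 2 PDAC subtype lists moved in opposite directions. The classical PDAC subtype list fell, with 21 of 28 members lower (mean log2 fold change -0.23, camera adjusted p = 0.00115, adjusted p = 0.675 with an estimated correlation). Its mean was -0.39, -0.13, -0.11 and -0.37 without Egfr KO PSC replicates 1, 3, 4 and 5, and the call was kept in each of these fits. It was lost with 1 surrogate variable (mean -0.11), and the mean was -0.42 with limma voom and -0.36 with the file-name number as a covariate. For the classical PDAC subtype score the exact permutation p was 0.27, unadjusted, and the groups overlapped. The score was 6.47 and 6.38 in Egfr KO PSC replicates 1 and 5 and 5.27 to 5.86 in the others, against 5.69 to 6.44 with Egfr WT PSCs. The transcription factor gene Onecut2 (173 ± 12.3 and 134 ± 14.4 CPM) and the secretory epithelial genes Agr2 (255 ± 87.1 and 136 ± 62.0 CPM) and Tff2 (204 ± 79.1 and 104 ± 50.2 CPM) were lower. The intestinal keratin gene Krt20 was higher (826 ± 96.7 and 1333 ± 742 CPM). The basal-like and squamous PDAC subtype list rose, with 21 of 29 members higher (mean log2 fold change 0.34, camera adjusted p = 0.00669, adjusted p = 0.626 with an estimated correlation). The exact permutation p of its score was 0.0476, unadjusted. Its call was lost with the macrophage score as a covariate (mean 0.23), and the mean was 0.52 with the fibroblast score as one. Of its members of lowest p, Dhrs9 (0.505 ± 0.193 and 1.35 ± 0.839 CPM), a retinoid dehydrogenase gene, was higher. The squamous genes Sfn (366 ± 47.7 and 264 ± 42.4 CPM) and Sprr2a1 (54.1 ± 21.3 and 24.8 ± 16.0 CPM) were lower. None of these 7 genes passed over all genes with edgeR or DESeq2.

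**Figure D2:**
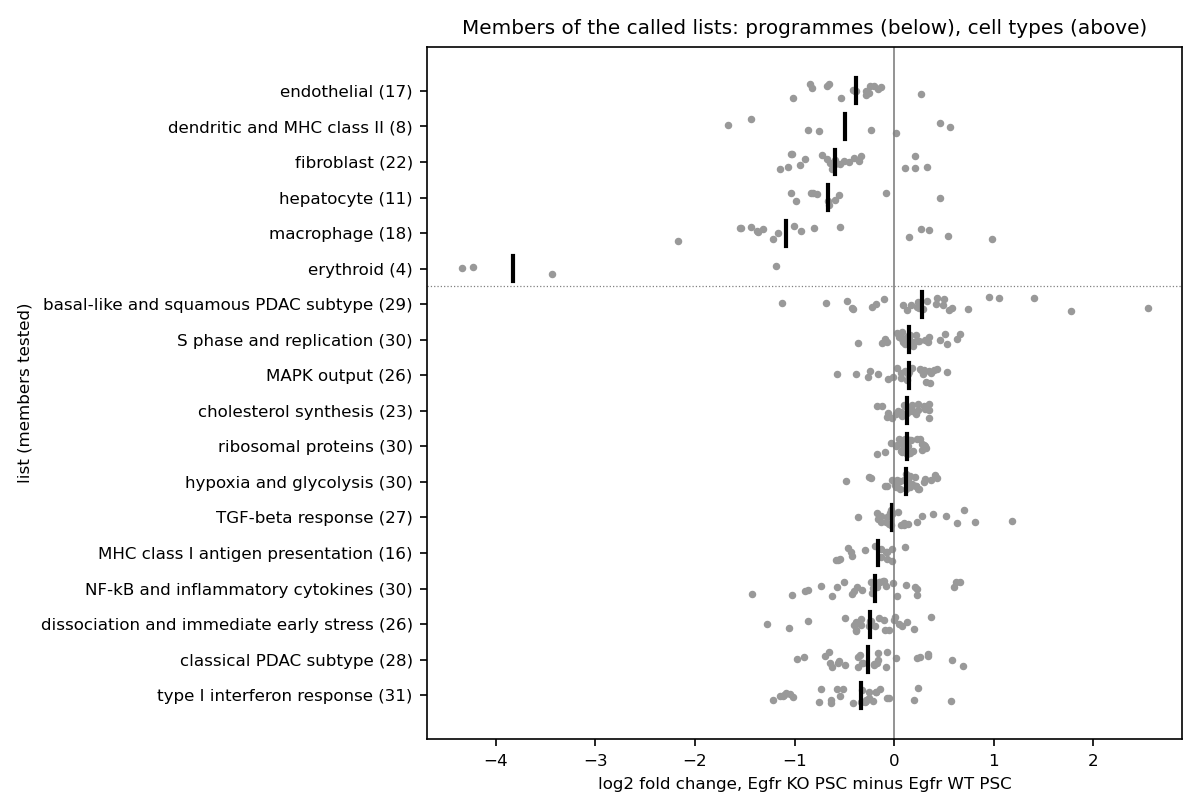
Log2 fold change (Egfr KO PSC minus Egfr WT PSC) of each tested member of the 18 called lists, one grey point per gene, with the median of the list as a black bar and cell type lists above the dotted line. The erythroid list stood furthest from 0, with a median of -3.83, and the medians of the programme lists lay between -0.34 and 0.28.

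The other lists that rose with Egfr KO PSCs did so by less than 0.2 in the mean log2 fold change. Ribosomal proteins were higher in 27 of 30 members (mean log2 fold change 0.13, camera adjusted p = 0.000274, adjusted p = 0.675 with an estimated correlation), among them Rps18 (940.2 ± 176 and 1167 ± 39.9 CPM) and Rpl5 (89.7 ± 10.6 and 109 ± 5.73 CPM). Cholesterol synthesis was higher in 18 of 23 members (mean 0.13, camera adjusted p = 0.00453, adjusted p = 0.675 with an estimated correlation), with Msmo1 at 197 ± 36.7 and 251 ± 47.6 CPM and Fdft1 at 176 ± 19.4 and 207 ± 22.04 CPM. MAPK output was higher in 19 of 26 members (mean 0.12, camera adjusted p = 0.0108, adjusted p = 0.675 with an estimated correlation). In it Myc was at 378 ± 42.3 and 501 ± 96.5 CPM and the chromatin gene Hmga1 at 1369 ± 426 and 1974 ± 241 CPM. Phlda1, an ERK-induced gene, was lower, at 73.6 ± 9.79 and 49.4 ± 18.2 CPM. S phase and replication was higher in 26 of 30 members (mean 0.19, camera adjusted p = 0.0238, adjusted p = 0.738 with an estimated correlation), with Uhrf1 at 73.3 ± 10.0 and 105 ± 39.2 CPM. Hypoxia and glycolysis was higher in 24 of 30 members (mean 0.10, camera adjusted p = 0.0386, adjusted p = 0.732 with an estimated correlation). The glucose transporter gene Slc2a1 was at 361 ± 76.8 and 479.7 ± 129 CPM and the hypoxia gene Car9 at 127 ± 34.5 and 90.9 ± 51.4 CPM. The TGF-beta response list was called higher (camera adjusted p = 0.0475, adjusted p = 0.675 with an estimated correlation), with a mean log2 fold change of 0.14 but a median of -0.026 and 14 of 27 members lower. Id3 and Id2 (379.7 ± 63.7 and 667 ± 219.8 CPM), targets of BMP and TGF-beta signalling, had the largest log2 fold changes of the list, and passed when adjusted over the list alone and with DESeq2 over all genes. The related gene Id1 was at 219.9 ± 44.2 and 315 ± 81.7 CPM. The receptor gene Tgfbr2 was at 84.4 ± 9.46 and 65.6 ± 12.1 CPM.

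Several of these calls ended when a single library was left out. The S phase, hypoxia and TGF-beta lists each kept the call in 5 of the 10 fits that left out 1 library, the MAPK list in 7, cholesterol synthesis in 8 and ribosomal proteins in 9. Without Egfr WT PSC replicate 3 all 6 of these lists lost it, and without Egfr KO PSC replicate 4 the MAPK, TGF-beta, S phase and hypoxia lists did. S phase also lost it without Egfr WT PSC replicate 2 or Egfr KO PSC replicates 2 or 3, MAPK without Egfr KO PSC replicate 3, and cholesterol synthesis without Egfr KO PSC replicate 5. Hypoxia also lost it without Egfr WT PSC replicate 4 or Egfr KO PSC replicates 2 or 5, and TGF-beta without Egfr WT PSC replicates 1 or 4 or Egfr KO PSC replicate 1. Some fits moved the mean log2 fold change by over 1.5 times. For the S phase and replication list it was 0.30, 0.012 and 0.29 without Egfr KO PSC replicates 1, 3 and 5. For the hypoxia and glycolysis list it was 0.22, 0.023 and 0.060 without Egfr WT PSC replicates 2, 3 and 4, and 0.16, 0.15, 0.064 and 0.0098 without Egfr KO PSC replicates 1, 3, 4 and 5. For the TGF-beta response list it was 0.092 without Egfr WT PSC replicate 3 and 0.050 without Egfr KO PSC replicate 4. For the cholesterol synthesis list it was 0.20 and 0.085 without Egfr WT PSC replicates 1 and 3, and 0.085 without Egfr KO PSC replicate 5. For the ribosomal proteins list it was 0.20 and 0.065 without Egfr WT PSC replicates 2 and 3, and 0.076 without Egfr KO PSC replicate 3. The mean of the MAPK output list lay between 0.081 and 0.16. Without Egfr KO PSC replicate 3 the test of the S phase list pointed the other way. Other settings ended calls as well. With 1 surrogate variable the S phase (mean -0.0044), MAPK (0.085) and TGF-beta (0.10) lists lost theirs. With the macrophage score as a covariate the TGF-beta (0.073) and cholesterol synthesis (0.028) lists did, and with the fibroblast score the S phase list did (0.22). Without Egfr WT PSC replicate 5 and Egfr KO PSC replicate 3 together, the S phase (0.048) and MAPK (0.11) lists lost the call. DESeq2 did not call the hypoxia (0.11) or TGF-beta (0.15) lists, and the hypoxia list also lost the call with the file-name number as a covariate (0.063). The TGF-beta list also lost it with a stricter filter (0.12) and a transcript length offset (0.13). The ribosomal proteins list kept its call in all 13 alternatives to the gene model, with means of 0.37, 0.25 and 0.076 with the fibroblast score, the macrophage score and 1 surrogate variable. Called means also moved by over 1.5 times with the fibroblast score for the MAPK (0.22), TGF-beta (0.29) and hypoxia (0.26) lists. They did so without Egfr WT PSC replicate 5 and Egfr KO PSC replicate 3 together for TGF-beta (0.23) and hypoxia (0.17). With limma voom they did so for hypoxia (0.18) and S phase (0.10).

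In all, camera called 12 of the 23 programme lists, 5 lower and 7 higher, and none of the 12 with an estimated correlation, where their adjusted p lay between 0.626 and 0.738. None passed with fry or with the exact test of scores adjusted over the lists. Unadjusted, the exact permutation p of the score was 0.0476 for the interferon list and for the basal-like and squamous list. For the other called programme lists it lay between 0.0794 (dissociation and immediate early stress) and 0.667 (S phase and replication). Leaving out Egfr WT PSC replicate 3 left 5 programme lists called, and leaving out Egfr KO PSC replicate 4 left 7. Adjusted over the list alone, 10 memberships in 6 programme lists passed. Among them were Ifi27, Id3, Id2, Icam1, Ctsl and Ascl2 once each, Csf1 in 2 lists, and the protease gene Mmp15, which was chosen after its values were seen. The fibroblast, macrophage and endothelial lists were lower with Egfr KO PSCs in the same libraries. The 11 programme lists not called had camera adjusted p of 0.0578 (matrix proteases and invasion), 0.182 (Wnt and stem cell), 0.19 (YAP-TEAD targets), and 0.304 (epithelial-to-stroma ligands). The others had 0.363 (unfolded protein response), 0.566 (oxidative phosphorylation), 0.77 (EGFR family, and epithelial junctions and keratins), 0.939 (mitosis and G2, and p53 targets) and 0.995 (epithelial-mesenchymal transition). The median and the mean log2 fold change differed in sign for Wnt and stem cell genes (0.10 and -0.071), junctions and keratins (0.049 and -0.014), p53 targets (0.036 and -0.058) and the epithelial-mesenchymal transition (0.092 and -0.12). The test pointed down for the Wnt list and up for the other 3, and it pointed down for mitosis and G2, whose median (0.0021) and mean (0.021) were positive. In the list of matrix proteases and invasion, Ctsl was higher. In that of Wnt and stem cell genes, the stem cell transcription factor gene Ascl2 was at 1.46 ± 0.518 and 0.500 ± 0.233 CPM. The unfolded protein response gene Xbp1 was at 53.6 ± 11.8 and 31.9 ± 8.07 CPM, and DESeq2 called both. Ptpn14 of the YAP-TEAD list was at 30.9 ± 5.35 and 22.2 ± 2.96 CPM, and Mmp2 of the epithelial-mesenchymal transition list at 3.68 ± 1.43 and 1.505 ± 0.823 CPM. The member of lowest p was Csf1 among the epithelial-to-stroma ligands, and Ndufb5 (85.0 ± 3.34 and 73.4 ± 5.402 CPM) in oxidative phosphorylation. It was Polk (37.4 ± 4.84 and 45.6 ± 4.12 CPM) among the p53 targets, and Tjp3 (22 ± 9.44 and 11.9 ± 5.86 CPM) among junctions and keratins. In mitosis and G2 it was Kif20a (85.8 ± 21.1 and 72.4 ± 10.8 CPM).

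Genes of red blood cells fell with Egfr KO PSCs, and so did 5 other cell type lists. The erythroid list fell most: all 4 tested members were lower, with a mean log2 fold change of -3.30 (camera adjusted p = 1.38e-14, adjusted p = 0.0248 with an estimated correlation). Its score was 1.68 ± 0.908 with Egfr WT PSCs and -1.63 ± 0.796 with Egfr KO PSCs, and the groups did not overlap (n = 5 each; exact permutation p = 0.00794, the smallest it can give). The globin genes were low in both groups. Hba-a1 was at 7.90 ± 5.21 and 0.727 ± 0.494 CPM, and Hba-a2 at 6.22 ± 3.34 and 0.324 ± 0.252 CPM. Hbb-bs was at 6.54 ± 4.93 and 0.315 ± 0.427 CPM, and Alas2, an enzyme of haem synthesis, at 0.583 ± 0.217 and 0.255 ± 0.0764 CPM. Adjusted over the list alone, all 4 passed, against 0 over all genes tested with edgeR. DESeq2 called Hba-a1, Hba-a2 and Hbb-bs over all genes (adjusted p = 4.58e-07, 0.000123 and 0.00219).

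The fibroblast list was lower in 18 of 22 members (mean log2 fold change -0.53, camera adjusted p = 2.39e-06, adjusted p = 0.231 with an estimated correlation). Its members of lowest p were the collagen genes Col1a1 and Col1a2 (39.0 ± 14.2 and 20.2 ± 9.29 CPM), Mfap5 (2.55 ± 1.13 and 1.15 ± 0.610 CPM) and Serping1 (19.3 ± 6.50 and 10.3 ± 5.05 CPM). The macrophage list was lower in 13 of 18 members (mean -0.79, camera adjusted p = 1.35e-05, adjusted p = 0.311 with an estimated correlation), with Ctss at 2.76 ± 2.61 and 0.948 ± 0.313 CPM. Without Egfr WT PSC replicate 2 the mean of the macrophage list was -0.44. The log2 fold change of Ctss was 0.33 with the macrophage score as a covariate, but that score includes Ctss itself. The endothelial list was lower in 16 of 17 members (mean -0.41, camera adjusted p = 0.000688, adjusted p = 0.388 with an estimated correlation), with Sox17 at 2.40 ± 0.482 and 1.19 ± 0.810 CPM. Without Egfr KO PSC replicate 3 the mean of the endothelial list was -0.74. The hepatocyte list was lower in 10 of 11 members (mean -0.59, camera adjusted p = 0.00138, adjusted p = 0.356 with an estimated correlation). It was led by the transferrin gene Trf, at 2674 ± 1081 and 1353 ± 441 CPM, which tissues other than the liver also express. The hepatocyte genes Ttr (4.55 ± 1.03 and 2.88 ± 1.93 CPM) and Alb were far below it, Alb at 0.293 ± 0.113 and 0.146 ± 0.172 CPM. The mean of the hepatocyte list was -0.35 and -1.05 without Egfr KO PSC replicates 4 and 5. The dendritic and MHC class II list was lower in 5 of 8 members (mean -0.49, camera adjusted p = 0.0251, adjusted p = 0.436 with an estimated correlation). H2-Aa was at 1.03 ± 0.386 and 0.325 ± 0.218 CPM, and H2-Ab1 at 2.38 ± 0.897 and 0.874 ± 0.522 CPM. Its call was lost without Egfr WT PSC replicate 5 (mean -0.34) and without Egfr KO PSC replicates 1, 2 or 5 (means -0.40, -0.43 and -0.43), and its mean was -0.78 without Egfr KO PSC replicate 3. With the fibroblast score as a covariate the endothelial list (mean -0.055), the hepatocyte list (mean -0.27) and the dendritic and MHC class II list (mean -0.22) lost the call. They also lost it with the macrophage score as a covariate (means -0.16, -0.51 and -0.23), and the dendritic list did with a stricter filter (mean -0.61). With limma voom and with the file-name number as a covariate, the mean was -0.77 and -0.65 for the endothelial list and -0.99 and -0.89 for the hepatocyte list. The endothelial mean was -0.64 without Egfr WT PSC replicate 5 and Egfr KO PSC replicate 3 together and -0.66 with 1 surrogate variable.

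**Figure D3:**
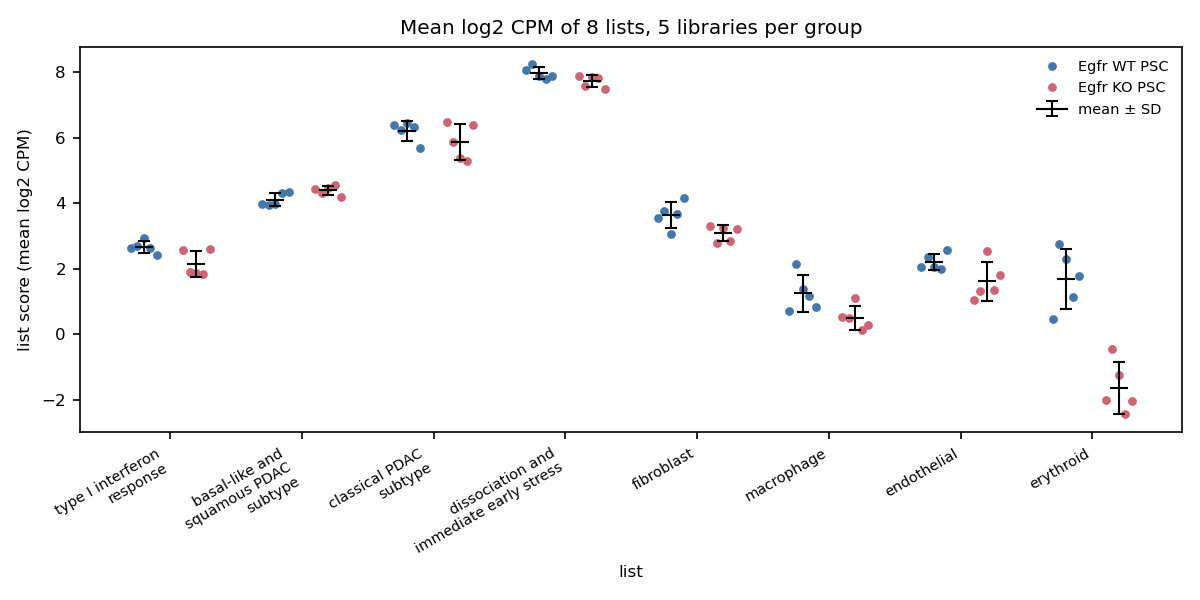
List score (mean log2 CPM of the members) of 8 called lists, one point per library, with the mean and SD of the 5 libraries of each group in black. The erythroid scores of the 2 groups did not overlap, and the interferon scores of Egfr KO PSC replicates 1 and 5 lay among those with Egfr WT PSCs.

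The other 8 cell type lists tested did not pass: mesothelial, islet, pericyte and smooth muscle, acinar, inflammatory CAF, adipocyte, myofibroblastic CAF and neutrophil, with camera adjusted p of 0.153, 0.153, 0.157, 0.214, 0.324, 0.377, 0.435 and 0.692. CAF stands for cancer-associated fibroblast. Of the 6 called lists, only the erythroid list passed with an estimated correlation or with fry (fry adjusted p = 0.0112). With the exact test of scores adjusted over the lists, none of the 14 passed, and the adjusted p of the erythroid list was 0.111. Adjusted over the list alone, 8 cell type memberships in 4 lists passed: the 4 erythroid genes, Col1a1, H2-Aa, H2-Ab1, and the neutrophil gene Ly6g, which was higher with Egfr KO PSCs and was chosen after its values were seen.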

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

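The tests in this part were chosen before the values were seen, as one check applied to 286 groups of 5 libraries, in which a library far from the other 4 of its group was looked for. Chance gives about 5% of groups, and 18 were found, of which 6 were in Egfr KO PSC replicate 1 and 4 in Egfr KO PSC replicate 3.

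In Egfr KO PSC replicate 1, Onecut3 was at 5.26 CPM (the others 2.73 to 3.30), Sprr2a1 at 52.6 CPM (14.3 to 23.8), Tjp3 at 22.02 CPM (7.21 to 11.0), Ptpn14 at 27.35 CPM (20.03 to 21.6) and Junb at 616 CPM (274 to 353). The score of the epithelial junctions and keratins list was 7.30 in that library (6.83 to 6.92 in the others).

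In Egfr KO PSC replicate 3, the scores of the ribosomal proteins list (9.18, others 8.88 to 8.94), the inflammatory CAF list (4.24, others 2.98 to 3.15) and the dendritic and MHC class II list (0.40, others -0.71 to -0.49) were the highest of the group. The protein-coding share was lowest there, at 96.5% against 97.3% to 97.6%. In Egfr KO PSC replicate 5, Rrm2, a subunit of ribonucleotide reductase, was at 548 CPM (113 to 236) and the p53 targets list at 5.03 (4.69 to 4.73). Hbb-bs was at 1.06 CPM in Egfr KO PSC replicate 2 (0.0195 to 0.231 in the others).

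Among the libraries with Egfr WT PSCs, Rad18 was lowest in replicate 3, at 34.9 CPM (43.3 to 45.5). In replicate 4, Agr2 was highest, at 406 CPM (199 to 249), and Sox17 lowest, at 1.56 CPM (2.45 to 2.76). The unfolded protein response list was lowest in replicate 5, at 6.37 (6.61 to 6.64), and the hepatocyte list in replicate 1, at 0.667 (1.30 to 1.52).

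Transcripts with no gene in the annotation used held 1.31% to 1.93% of the counts of a library, and the most abundant of them had a mean of 7706 CPM. Its difference between the groups did not pass the test (log2 fold change -0.11, edgeR adjusted p = 0.996). Of 1249 such transcripts tested, edgeR called 0, and 49 had an unadjusted p under 0.05. Their genes were not identified.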

How the results depend on the processing

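The tests with the macrophage score, with 1 surrogate variable and without Egfr WT PSC replicate 5 and Egfr KO PSC replicate 3 together were chosen after the data were seen. Each of these 2 libraries was the highest of its group on the first principal component. The count of 0 genes in either direction from edgeR held with median-of-ratios size factors, a stricter filter, a transcript length offset and protein-coding genes alone. It also held with each of 4 covariates (genes detected, fibroblast score, file-name number, macrophage score), and without these 2 libraries together. The smallest edgeR adjusted p was 0.979 with the macrophage score and 0.33 with the fibroblast score, against 0.105 in the main fit. DESeq2 called 42 higher and 85 lower, voom 1 higher and 2 lower, and edgeR 1 lower with no filter and 1 lower with 1 surrogate variable. Leaving out 1 library gave 0 to 1 higher and 0 to 4 lower, with 1 higher without Egfr KO PSC replicate 3, 4 lower without Egfr KO PSC replicate 1 and 2 lower without Egfr WT PSC replicate 5. The cause was not tested. Of the 104 named genes, 21 passed in some alternative, in 30 results.

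The number of programme lists called, 12 in the main fit, was 7 with 1 surrogate variable and 7 with the macrophage score. It was 0 with camera with an estimated correlation, with fry and with exact permutation of list scores. Without 1 library they numbered 5 to 12, the lowest without Egfr WT PSC replicate 3, with 7 without Egfr KO PSC replicate 4. The number of cell type lists called, 6 in the main fit, was 3 with the fibroblast score as a covariate, 1 with an estimated correlation, 1 with fry and 0 with exact permutation. It lay between 5 and 8 without 1 library. The counts with the fibroblast or macrophage score include lists not called in the main fit. Of the 6, the macrophage and erythroid lists kept the call with the fibroblast score. The cause was not tested, except that a covariate's own list was not counted as called with it. The interferon and erythroid lists kept their direction and call in all 13 alternatives to the gene model and in all 10 fits that left out 1 library, and the fibroblast and macrophage lists in the 12 that could be run and in all 10. Of the 18 called lists, 14 lost the call in some such fit, and 11 of the lists not called were called in one.

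Opposite directions arose in 9 named genes that had not passed (30 results), in lists (56 results, 1 of them of a called list) and in library measures (11 results). The values are log2 fold changes, and for a list the mean of its members, whose sign can differ from that of its test. With median-of-ratios size factors, these were Epcam (0.0055), and the epithelial-mesenchymal transition list (-0.11). With no low-count filter, these were the epithelial-mesenchymal transition list (-0.11) and p53 targets list (-0.061). With a transcript length offset, these were the epithelial-mesenchymal transition list (-0.14). With DESeq2, these were Epcam (0.0055), and the epithelial-mesenchymal transition list (-0.11) and mitosis and G2 list (0.029). With limma voom and sample weights, these were Areg (-0.054), Egf (0.079) and Epcam (0.037), and the epithelial junctions and keratins list (-0.081), EGFR family receptors and ligands list (-0.098), mitosis and G2 list (-0.011) and p53 targets list (-0.090). With protein-coding genes alone, these were Epcam (0.0082), and the mitosis and G2 list (0.040). With genes detected as a covariate, these were Epcam (0.0086). With the fibroblast score as a covariate, these were Egfr (-0.11), Erbb3 (-0.051), Epcam (0.22) and Pecam1 (0.16), and the epithelial-to-stroma ligands list (0.13), myofibroblastic CAF list (0.28), inflammatory CAF list (0.36), pericyte and smooth muscle list (0.35), neutrophil list (0.19) and islet list (-0.18). With the file-name number as a covariate, these were Epcam (0.091), and the oxidative phosphorylation list (-0.022) and p53 targets list (-0.12). With Egfr WT PSC replicate 5 and Egfr KO PSC replicate 3 left out together, these were Egf (0.047) and Epcam (0.11), and the EGFR family receptors and ligands list (-0.077), YAP-TEAD targets list (0.014), p53 targets list (-0.076) and myofibroblastic CAF list (0.039). With 1 surrogate variable as a covariate, these were the epithelial-mesenchymal transition list (-0.16) and acinar list (0.12). With the macrophage score as a covariate, these were Ctss (0.33), Egfr (-0.17), Erbb3 (-0.070), Epcam (0.14) and Pecam1 (0.082), and the epithelial-mesenchymal transition list (-0.039), EGFR family receptors and ligands list (0.10), mitosis and G2 list (0.093), inflammatory CAF list (0.056) and neutrophil list (0.38). Ctss is a member of the macrophage list, whose score as a covariate therefore includes it. With fry, these were the epithelial-mesenchymal transition list (-0.12) and p53 targets list (-0.058). With exact permutation of list scores, these were the epithelial junctions and keratins list (-0.022), epithelial-mesenchymal transition list (-0.089) and p53 targets list (-0.075). Over the fits without 1 library, the ranges were Btc (-0.0041 to 0.17), Egf (-0.24 to 0.059), Trp53 (-0.074 to 0.059) and Epcam (-0.17 to 0.16). For lists they were the epithelial junctions and keratins list (-0.11 to 0.030), the epithelial-mesenchymal transition list (-0.21 to 0.012), the EGFR family receptors and ligands list (-0.023 to 0.20), the S phase and replication list (0.012 to 0.30), the mitosis and G2 list (-0.15 to 0.14), the p53 targets list (-0.14 to -0.015), the epithelial-to-stroma ligands list (-0.17 to 0.026), the myofibroblastic CAF list (-0.17 to 0.075), the inflammatory CAF list (-0.60 to -0.031) and the neutrophil list (-0.41 to 0.061). Without Egfr KO PSC replicate 3 the S phase test turned, with a mean of 0.012. The group differences of library measures ranged over the total estimated count in genes (-1301000 to 2156400) and genes detected (-116 to 198). The cause was not tested. On simulated data edgeR called 16% of the genes changed 1.5-fold and 48% of those changed 2-fold, so smaller changes in single genes would mostly be missed at this number of libraries.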

Other observations

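The tests of all 14 held-out tuft cell genes and of other splits of the libraries were written before their values were looked at, although a table of all genes already existed and Dclk1 stood in the Wnt and stem cell list already tested, so the tuft result is exploratory, and all other tests in this part were chosen after the result was seen. Genes of tuft cells, chemosensory epithelial cells that arise in the pancreas during early neoplasia, were lower with Egfr KO PSCs. The pattern was noticed in these data among 12 genes, and a list of 30 tuft cell genes was then written down. Of the 26 above the filter, 25 were lower and 20 had an unadjusted p under 0.05, with a mean log2 fold change of -2.16, which includes the 12 in which the pattern was noticed. Of the 14 held out, 13 were lower, 8 of them with an unadjusted p under 0.05, with a mean log2 fold change of -1.21 and a median of -0.90. These 14 mark the same cell type in the same libraries as the 12. Neither these counts nor the exact permutation p of held-out genes given below is therefore a separate check on the selection of the 12. The score given next is that of the 14. Their score was 3.36 in Egfr WT PSC replicates 2 and 3 and 1.92 to 2.33 in the other 3. It was 2.39 in Egfr KO PSC replicate 1, above Egfr WT PSC replicates 1, 4 and 5, and 0.81 to 1.58 in the other 4, so the groups overlapped. The signalling genes Trpm5 (5.57 ± 3.57 and 1.58 ± 0.487 CPM with Egfr WT and Egfr KO PSCs), Gnat3 (5.51 ± 4.36 and 0.398 ± 0.602 CPM) and Rgs13 (7.67 ± 5.53 and 0.651 ± 0.903 CPM) and the lineage transcription factor gene Pou2f3 (1.44 ± 1.26 and 0.310 ± 0.337 CPM) were all low. Ptpn6 was the 1 gene higher, and only Avil, Dclk1, Ptgs1 and Ptpn6 reached 10 CPM in both groups. edgeR called 0 of the 26 and DESeq2 called 13, of which 3 were among those held out.

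Blood or immune cell RNA could carry such genes, because several are shared with blood cells. The 5 held-out genes left without those known in blood cells (Pou2f3, Sh2d6, Avil, Dclk1 and Tas1r3) differed in their score by -1.29 (SE 0.444; exact permutation p 0.0238), but by -0.9054 (SE 0.586) with the macrophage score as a covariate, so that RNA cannot be told apart from a change in the epithelial cells; earlier forms of this test, without the covariate or with Matk, Bmx and Il17rb, had argued against it. All 14 held-out genes had an exact permutation p of 0.0397, and without any 1 of the 10 libraries the mean was -1.821 or below for all 26 and -0.98 or below for those held out. Without both Egfr WT PSC replicates 2 and 3, however, 10 of the 14 were lower, with a mean of -0.51 (exact permutation p 0.143), and the 5 genes had a mean of -0.69 (exact permutation p 0.107); these libraries also had the highest erythroid (2.75 and 2.30) and macrophage scores (2.16 and 1.37). A programme that was high in these 2 libraries by chance therefore stays open, as do host tuft cells in an epithelial gate whose markers are not given and fewer carcinoma cells in a tuft-like state with Egfr KO PSCs, which were not tested.

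The interferon list may be lower because the libraries with Egfr KO PSCs hold less macrophage RNA. With the macrophage score as a covariate the score difference was -0.4973 (SE 0.277), against -0.516 (SE 0.196) without it, so the size hardly moved while the error grew, and that source cannot be told apart from a change in the carcinoma cells. Without any 1 of the 10 libraries the mean log2 fold change of the list was -0.3855 or below, which argues against a single library, by a rule that was changed after this result was seen. A lower interferon response of the carcinoma cells themselves stays open and was not tested.

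The erythroid genes might be lower because the sorts with Egfr WT PSCs held fewer carcinoma cells. The erythroid score difference lay -2.685 (SE 0.487) from the mean of the fibroblast, macrophage and endothelial ones. This test replaced a first form, against the acinar list alone, after its result was seen. It cannot decide the question, because a lower share need not move all list scores alike when carcinoma cells also express some members. The pericyte and smooth muscle (-0.31, SE 0.32), neutrophil (-0.14, SE 0.30) and acinar (0.23, SE 0.53) score differences lay within 1 SE of 0. A lower share of carcinoma cells therefore stays open. Library depth is argued against, since the mean total count differed by 0.6059%. More red blood cells in the tumours or sorts with Egfr WT PSCs, from bleeding, vessels or the handling of the tissue, stay open and were not tested.

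Of the 126 possible splits of the 10 libraries into 5 and 5, 100 were examined, the real one included. Of these 100, 18 gave at least the 1426 genes at an unadjusted p under 0.05, the highest other split giving 3196. Counting the real split in the same way, 15 gave at least 12 programme lists (highest other 15) and 40 at least 6 cell type lists (highest other 13). The medians over the other splits were 638 genes at that unadjusted p, 8 programme lists and 5 cell type lists. Chance can be excluded for none of these 3 counts. DESeq2 was not run on the splits, so its 127 calls were not compared with other splits. At least 0 genes past the adjusted threshold is met by all 100 whatever the data (highest other 2), so that count decides nothing. A split with 3196 such genes points to a structure of the libraries other than the groups; the first principal component held 25.4% of the variance and its difference between the groups did not pass (exact permutation p = 0.23), while the second held 17.7% and differed, at 20.4 ± 17.1 with Egfr WT PSCs and -20.4 ± 26.1 with Egfr KO PSCs (exact permutation p = 0.0317, unadjusted).

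The score of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) varied between libraries, with Ddx3y at 1.33 to 8.01 CPM and Xist at 0 to 0.224 CPM. Across the 10 libraries it correlated with the endothelial score (Pearson r 0.859, permutation p = 0.00221, adjusted p = 0.0189; Spearman rho 0.830, permutation p = 0.00444, adjusted p = 0.0508) and with the pericyte and smooth muscle score (r 0.827, permutation p = 0.0027, adjusted p = 0.0189; rho 0.806, permutation p = 0.00725, adjusted p = 0.0508), out of 14 relations computed. Without the 2 libraries farthest from the median, r was 0.769 and 0.707. With both scores centred within each group, r was 0.897 for the endothelial score (exact permutation within groups p = 0.000903, adjusted p = 0.0126) and 0.81 for the pericyte and smooth muscle score (exact p = 0.0105, adjusted p = 0.0367). The inflammatory CAF and the dendritic and MHC class II scores also passed there (adjusted p = 0.0256 each). On ranks within groups none of the 14 passed, with adjusted p of 0.134 for the endothelial and 0.305 for the pericyte and smooth muscle score. The difference of the Y-linked score between the groups did not pass (-0.376, SE 0.451, exact permutation p = 0.413).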
